A study of Homo sapiens with 8 samples.

How the data were processed

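RNA was measured on 8 Illumina expression arrays, 1 per sample, from the human embryonic stem cell line H1. The labels place 2 arrays in each of 4 groups: cells that received a control lentivirus with the EF1a promoter, or a lentivirus meant to overexpress NANOG, OCT4 (the protein encoded by POU5F1) or SOX2. Per the labels' protocols, the cells grew without feeder cells on Matrigel in mTeSR medium and received virus with polybrene. Trizol-extracted, DNase-treated RNA was then copied into biotin-labelled cRNA with an Illumina TotalPrep kit. The time between transduction and harvest is not given in the sources used here. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

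The values used were the authors' processed intensity values, deposited for 47323 probes on each of the 8 arrays. Their unit is brightness on a linear scale, from 86.3 to 22884, and every array had a median of 117.1. The sorted values of the 8 arrays differed by at most 2.3, so the authors had quantile normalized them. The tool they used is not given in the sources used here. A deposited table of signals before normalization has 16 columns, 8 of signal and 8 of detection p-values, whose names match no sample's label. Those columns were not used in any step.

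The design fixed before the data were examined called for detection p-values in the background correction and in the filter. As these could not be assigned to samples, the design's fallback was used: normexp background correction with an offset of 50, in limma 3.58.1 under R 4.3.3, and then log2. No further normalization between arrays was applied. In place of the detection filter, a probe was kept when its intensity exceeded 123.7, the 60th percentile of all intensities, on at least 2 of the 8 arrays. This left 21828 probes.

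Probe names came from a table of the array platform's annotation. It gave 1 gene symbol for 30113 probes, several for 8 and none for 17202, and probes with several or none were not named. Of the probes with 1 symbol, 30074 matched a RefSeq gene table of the human assembly GRCh38.p14 by gene number and 39 did not, and 0 symbols were updated. That table served for names only, and no coordinates are given because the build behind the probe design is not given in the sources used here. Each gene was represented by the probe with the highest mean over the 8 arrays, which gave 12436 genes, 3160 of them with more than 1 probe past the filter. Where a gene's other probe pointed the opposite way, this is said beside the gene. Members of families with near-identical sequences, such as CSH2, HLA-B and the metallothionein genes, are uncertain, because a probe can bind their relatives too.

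All 8 arrays entered 1 limma model (lmFit and eBayes) with a mean per group, so the groups shared 1 estimate of the spread, with 4 residual and 4.39 prior degrees of freedom. The median residual SD was 0.139 on the log2 scale. Tests were two-sided, with Benjamini-Hochberg adjustment over the 12436 genes and a threshold of 0.05. Each factor was compared with control, and the factors with each other. Fold changes are ratios of background-corrected intensities with the offset of 50 included, which understates the change of dim genes. Where a gene's probe lay under the filter intensity on both arrays of 1 group, only a bound is given. It is the bright group's mean over the dim group's mean, each dim array taken at the filter intensity or at its own value, whichever was higher. The precision of every value is limited by the number of arrays, 2 per group.

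The 32 gene lists were fixed before the data were examined. They cover pluripotency, signalling, germ layers, germ cells, stress, metabolism and the cell cycle, and include fibroblast and blood or endothelial markers as other cell types. A total of 2 list symbols matched no gene, and all 32 lists had the minimum of 5 measured genes. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists of a comparison. The test was repeated with an estimated correlation and with fry, which asks whether a list's genes moved, on balance, one way. Named genes were also fixed by rule. They are the 3 factors, the 10 largest rises and 10 largest falls past the threshold with no overlap between the groups' arrays, and up to 4 passing members of each list. For each pair of factors the rule adds the 5 largest differences in each direction and the 5 largest shared changes. Genes with only a LOC or open reading frame name were counted and not named.

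Comparisons with the same 2 control arrays share their chance values. Unchanged groups were therefore simulated 100 times against shared controls, and the overlap of independent lists was computed per direction.

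The procedure was tested on simulated data for the 12436 genes, with 20 draws and 200 genes changed per factor. Each gene had its control mean and 1 spread pooled over the groups, and noise was independent between genes. The rates that follow, those for lists included, therefore do not reflect the wider spread of the SOX2 arrays or correlation between genes. For NANOG against control it recovered 36.6% of genes changed 1.5-fold, 92.6% of those changed 2-fold and 99.8% of those changed 4-fold, and 6.76% of its calls were false. For OCT4 against control these values were 35.5%, 91.3%, 98.9% and 5.95%. For SOX2 against control they were 34.9%, 93.7%, 99.8% and 6.40%. Between factors, 1.5-fold changes were recovered in 51.7% (NANOG and OCT4), 50.2% (NANOG and SOX2) and 51.9% (OCT4 and SOX2) of cases. In simulated data for the first comparison with no list shifted, camera called a mean of 0.3 lists, and a cell cycle list shifted by -0.3 on the log2 scale was called in 20 of 20 draws.

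Alternatives tried were no background correction, which equals the authors' values on the log2 scale, no filter, every probe tested, a fold threshold of 1.5, an intensity trend in the prior variance, array weights, only the 2 groups compared in the fit, the replicate number as a block, and each array left out in turn. An offset of 16, a filter on all 8 arrays, and the omission of SOX2 replicate 2 as an array in doubt were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.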

Results

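Expression was profiled in 8 samples of H1 human embryonic stem cells, with 2 arrays each for cells given a control lentivirus and for cells given NANOG, OCT4 or SOX2 lentivirus. NANOG, OCT4 and SOX2 are the core transcription factors of the pluripotent state, and the design asks how the transcriptome responds when each is expressed from a vector. After filtering, 12436 genes were compared. Replicate arrays correlated across genes at 0.988 (control), 0.996 (NANOG), 0.991 (OCT4) and 0.969 (SOX2), where genes are not independent replicates. Between the 2 arrays of a group, 44 genes differed by more than 1 log2 unit in the control group, 0 in the NANOG group, 42 in the OCT4 group and 303 in the SOX2 group. The first principal component held 47.8% of the variance and the second 25.3%.

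The transduced factors were examined first. No probe of NANOG, POU5F1 or SOX2 had a higher mean log2 intensity on the arrays labelled with its own factor than on the control arrays. SOX2 probe ILMN_2177156 fell by 1.15 on the log2 scale (SE 0.18, adjusted p = 0.00840), from 959 and 1337 in control to 565 and 502. SOX2 probe ILMN_1770635 was at -0.77 (SE 0.24, adjusted p = 0.0910). For POU5F1 on the arrays labelled OCT4, probe ILMN_1705546 was at -0.95 (SE 0.16, adjusted p = 0.0981) and probe ILMN_1665632 at -0.01 (SE 0.16, adjusted p = 1.00). ILMN_1665632 read only 120 to 146 over the 8 arrays, close to the filter intensity, against 1501 to 3945 for ILMN_1705546. Neither its value nor its sign can therefore show whether POU5F1 changed. For NANOG on its own arrays, the log2 changes were -0.22 (SE 0.21, adjusted p = 0.735) for ILMN_1659013 and -0.29 (SE 0.13, adjusted p = 0.390) for ILMN_3307710. The positions of these probes are not given in the sources used here, and a probe outside the transduced sequence checks nothing about the labels, so samples are called by their labels throughout. On arrays labelled SOX2, the NANOG probe ILMN_3307710 fell by 0.57 (adjusted p = 0.0392), while the brighter NANOG probe ILMN_1659013 was at -0.33 (adjusted p = 0.382). Left-out arrays changed 2 of the calls on a factor's own arrays: POU5F1 probe ILMN_1705546 passed without SOX2 replicate 1 or SOX2 replicate 2 (adjusted p = 0.01 for both), and SOX2 probe ILMN_1770635 passed without SOX2 replicate 2 (-1.12, adjusted p = 0.00631). The sign of ILMN_1659013 turned without control replicate 1 (0.04), and that of ILMN_1665632 turned without control replicate 2 (0.03) or OCT4 replicate 2 (0.19).

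**Figure D1:**
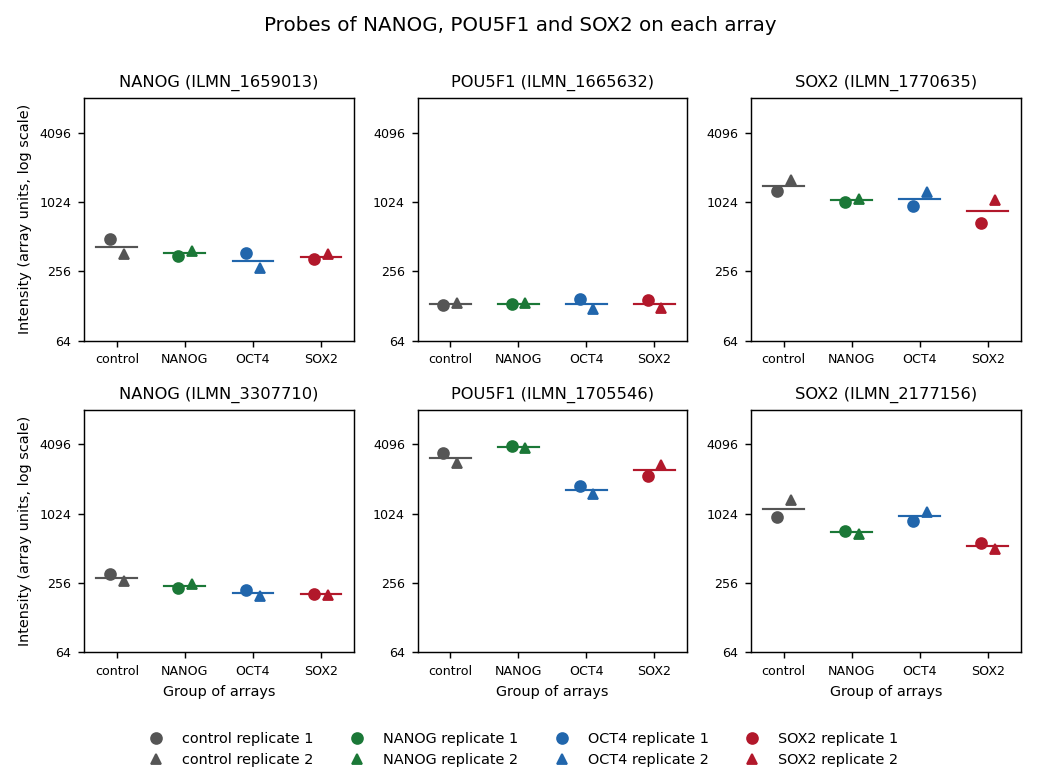
Intensity (linear units on a log axis) of the 6 probes for NANOG, POU5F1 and SOX2 on each of the 8 arrays, by group, with circles for replicate 1, triangles for replicate 2 and a bar at the geometric mean of the 2 arrays. No probe has a higher geometric mean on the arrays labelled with its own factor than in control, although POU5F1 probe ILMN_1665632 reads 146 on OCT4 replicate 1 against 131 and 136 in control. These readings of ILMN_1665632 lie close to the filter intensity. SOX2 probe ILMN_2177156 drops from 959 and 1337 to 565 and 502.

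In cells labelled NANOG, DPPA3, LEFTY1 and GDF3 had the largest rises in measured log2 change among the genes that passed. Genes given below only as a bound may have risen more than LEFTY1 or GDF3. DPPA3, which protects the maternal genome from demethylation and marks germ cells and naive pluripotency, rose 17.3-fold (log2 change 4.11, SE 0.17, n = 2 against 2, adjusted p = 6.77e-05), from 163 and 130 to 2018 and 1642. LEFTY1, a secreted inhibitor of nodal, rose 9.56-fold (log2 3.26, SE 0.44, adjusted p = 0.00778), and GDF3, a TGF-beta family ligand of pluripotent cells, rose 9.19-fold (log2 3.20, SE 0.45, adjusted p = 0.00870). The placental lactogen gene CSH2 rose at least 6.47-fold, the cystatin gene CST1 at least 6.10-fold and DNAAF11, needed for dynein arm assembly, at least 4.75-fold. SPOCK2, a matrix proteoglycan (log2 2.73), LEFTY2, a further nodal inhibitor (2.53), PPP2R2C, a phosphatase 2A subunit (2.51), and QPCT, a glutaminyl cyclase (2.48), completed the 10 largest rises. The largest falls were in SFRP1, a secreted WNT antagonist (log2 -2.46, SE 0.42, adjusted p = 0.0199), and SOX21, a neural progenitor transcription factor (log2 -2.19, SE 0.26, adjusted p = 0.00462). They were followed by the basement membrane gene FRAS1 (-1.53), the adhesion gene ALCAM (-1.49), the engulfment receptor gene MEGF10 (-1.47, with a further probe at -0.41), GPR176 (-1.43), STMN3 (-1.36), the amino acid transporter gene SLC7A5 (-1.35), the deubiquitinase gene USP9X (-1.35) and TTYH1 (-1.35). SFRP1, LEFTY1 and LEFTY2 also differed between replicates of other groups. SFRP1 read 468 and 1173 in control and 548 and 984 with OCT4, against 175 and 162 with NANOG. LEFTY1 read 195 and 139, 282 and 123, and 1117 and 1299 in the same order, and LEFTY2 355 and 157, 285 and 126, and 1120 and 1158. In limma's test 451 genes changed, 341 up and 110 down, of which 145 rose and 29 fell at least 2-fold, and 2093 genes had an unadjusted p under 0.05. Rises made up 75.6% of these calls, 59.8% with only the 2 groups in the fit (730 up and 491 down) and 58.4% with array weights (743 up and 529 down). The number of genes changed was 92 without control replicate 2, 49 without NANOG replicate 1 (49 up and 0 down), 72 without NANOG replicate 2, 1094 without SOX2 replicate 1 and 1093 without SOX2 replicate 2. Of 68 named genes that passed against control, 9 passed with any 1 array left out, namely DPPA3, CSH2, CST1, SPOCK2, DNAAF11, PPP2R2C, NLRP7, APOB and ABCG2. The others were lost without some array (59 without NANOG replicate 1, 56 without NANOG replicate 2, 51 without control replicate 2, 21 without control replicate 1 and 10 without either OCT4 array, at adjusted p up to 0.397), and all 68 kept their sign. With all arrays kept, 19 of the 59 were also lost under another setting, LEFTY2 among them. Of 18 called genes with a further probe, 10 had no further probe that passed, MEGF10, USP9X and TTYH1 among them.

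The naive pluripotency list, genes of the state before implantation, was called higher in cells labelled NANOG (camera adjusted p = 5.11e-07; adjusted p = 0.286 with an estimated correlation). Of its 9 measured members 4 rose, 0 fell and the others did not pass: DPPA3, DPPA5 (log2 1.63, SE 0.25), NLRP7 (1.44, SE 0.15) and KLF2 (0.87, SE 0.12), with 5 rises adjusted over the list alone. Of 11 germ cell genes 3 rose and 0 fell, also 3 adjusted over the list alone: DPPA3, which is on both lists, the RNA-binding gene DND1 (log2 0.97) and the transcription factor gene TFAP2C (0.81) (camera adjusted p = 0.000953; adjusted p = 0.286 with an estimated correlation). Metallothioneins bind zinc and copper, and their list also holds SLC30A1 and MTF1. Of 9 measured genes on it, 4 rose and 0 fell: MT1F (log2 1.40, SE 0.24), MT1H (1.26), MT1G (0.91) and MT1M (0.87). Adjusted over the list alone, 6 rose (camera adjusted p = 1.93e-05, and adjusted p = 0.286 with an estimated correlation). Of 8 nodal and activin targets 3 rose, GDF3, LEFTY1 and LEFTY2, and 5 adjusted over the list alone (camera adjusted p = 0.00116; adjusted p = 0.522 with an estimated correlation). Over the 8 genes of that list, the median difference of replicate 1 minus replicate 2 was 0.47 log2 within the control group and 1.15 within the OCT4 group. Of 7 primitive streak genes 1 rose, the ligand gene WNT3 (log2 0.94, SE 0.20), and 5 adjusted over the list alone (camera adjusted p = 0.00159; adjusted p = 0.286 with an estimated correlation). Of 13 FGF and ERK feedback genes 3 rose, the phosphatase gene DUSP5 (log2 1.58, SE 0.28), the inhibitor gene SPRED2 (1.38, SE 0.18) and the transcription factor gene ETV5 (0.99, SE 0.21), with 3 adjusted over the list alone (camera adjusted p = 0.00184; adjusted p = 0.286 with an estimated correlation). Of 12 trophectoderm and amnion genes 4 rose and 1 fell, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.0255; adjusted p = 0.286 with an estimated correlation). The risers were TFAP2C, the efflux transporter gene ABCG2 (at least 3.58-fold), the GABA receptor subunit gene GABRP (log2 1.39) and IGFBP3, which binds insulin-like growth factors (1.36), and the homeobox gene DLX5 fell.

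The cell cycle list was called lower in cells labelled NANOG, with 25 of its 31 measured genes below control. Of 31 measured, 0 rose and 3 fell: CCND1, a driver of the G1 phase (log2 -0.90, SE 0.14), the topoisomerase gene TOP2A (-0.68, SE 0.13) and the mitotic kinase gene AURKA (-0.62, SE 0.12), with 7 falls adjusted over the list alone (camera adjusted p = 7.45e-05; adjusted p = 0.340 with an estimated correlation). Of 25 neuroectoderm genes only SOX21 fell, with 5 adjusted over the list alone (camera adjusted p = 0.0393; adjusted p = 0.650 with an estimated correlation). Pluripotency genes gave no call (camera adjusted p = 0.914): of 28 measured, GDF3 and SCGB3A2 rose, and PODXL, a cell surface sialomucin (log2 -1.03), and POLR3G, a subunit of RNA polymerase III (-0.58), fell. With all arrays kept, 6 of 10 other settings ended the SCGB3A2 call and 3 the POLR3G call, and the further probes of PODXL and POLR3G did not pass. The neuroectoderm call was lost without control replicate 2 (adjusted p = 0.221), NANOG replicate 1 (0.0907), SOX2 replicate 1 (0.0785) or SOX2 replicate 2 (0.0786), with no background correction (0.0609) and with no filter (0.161), over a range of 0.00341 to 0.221. The trophectoderm call was lost without control replicate 1 (0.129) and with no filter (0.368; range 0.00472 to 0.368), and the germ cell call with the filter on all 8 arrays (0.284; range 0.000202 to 0.284). The DPPA3, NLRP7 and ABCG2 calls held with any 1 array left out. All other members named from these lists were lost without at least 1 of the NANOG or control arrays, at adjusted p up to 0.374, CCND1, TOP2A and AURKA among them. Other settings with all arrays kept also ended calls of LEFTY2, DLX5, ETV5, WNT3, GABRP, TFAP2C, AURKA and MT1G. The 23 uncalled lists, this one included, had adjusted p from 0.123 to 0.953. None of the lists called in any comparison held with an estimated correlation, and fry called 10 lists here, 7 of them called by camera as well.

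**Figure D2:**
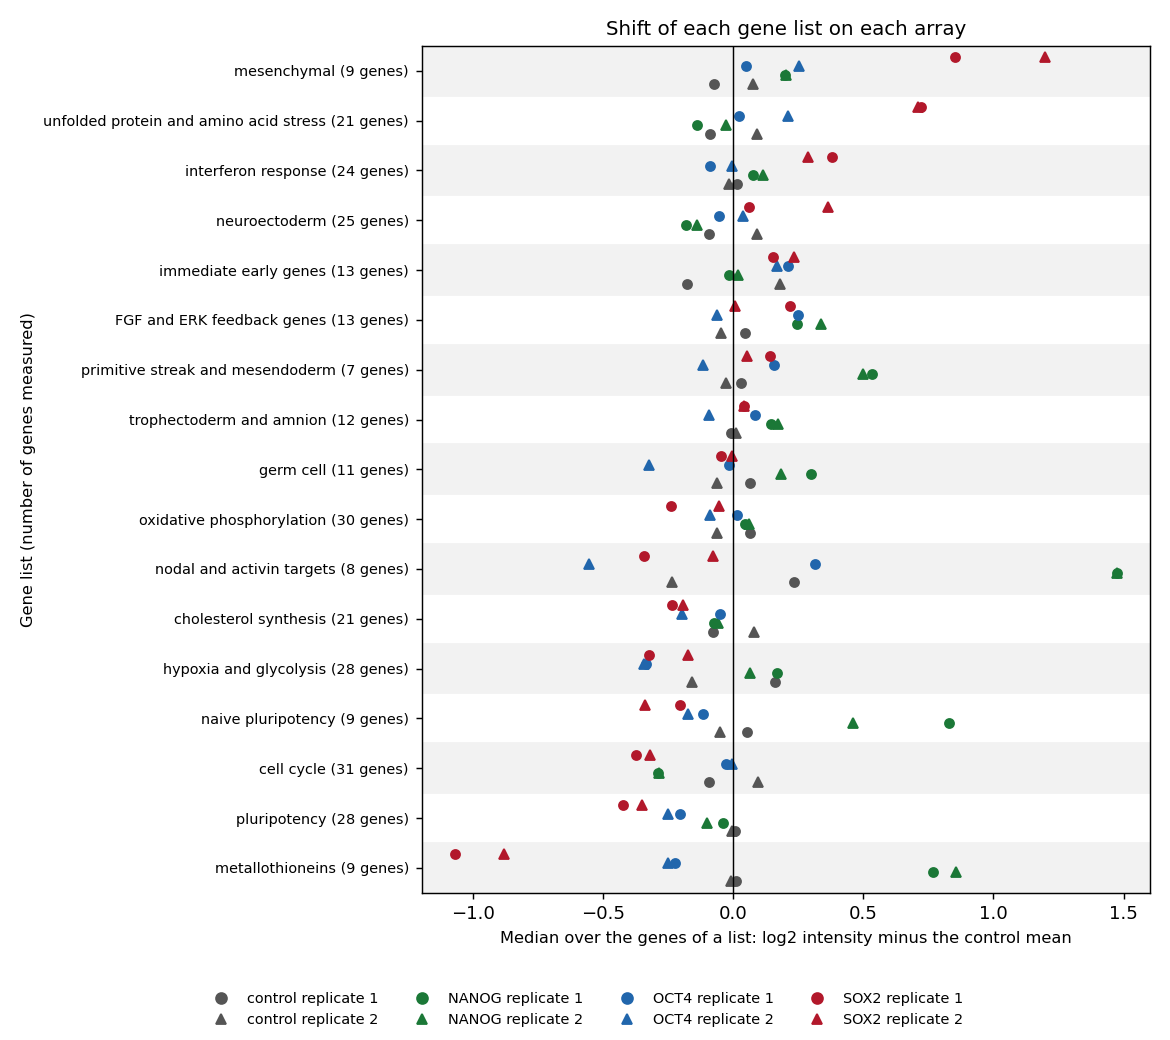
Median over each list's measured genes of log2 intensity minus the control mean (log2 units), for the 17 gene lists called against control for at least 1 factor, with 1 marker per array (circles for replicate 1, triangles for replicate 2; grey control, green NANOG, blue OCT4, red SOX2). The nodal list lies at 1.48 on both arrays labelled NANOG, and the metallothionein list at 0.77 and 0.85 on them and at -1.07 and -0.88 on the arrays labelled SOX2.

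In cells labelled OCT4, few genes changed, and the largest rises were in genes outside the fixed lists. CNRIP1, which binds the cannabinoid receptor, rose 5.29-fold (log2 2.40, SE 0.12, n = 2 against 2, adjusted p = 0.000316), from 219 and 212 to 1008 and 911. COL5A2, a fibrillar collagen gene, rose 3.99-fold (log2 2.00, SE 0.15, adjusted p = 0.00305), the transcription factor gene EBF3 at least 3.34-fold and UCP1, the uncoupling protein of brown fat, at least 3.30-fold. LRRC3B (log2 1.76), PGM2L1, a sugar phosphate enzyme (1.71), the potassium channel gene KCNJ2 (1.55), ZDHHC22 (1.49), ELMOD1 (1.49) and the neuronal vesicle gene NSG1 (1.47) followed. A total of 8 genes fell. They were the potassium channel gene KCNK12 (log2 -1.36, SE 0.16, adjusted p = 0.0169), LITAF (-1.24), RPRML (-1.19), HESX1, a homeobox gene of the early forebrain (-1.17), the sulfotransferase gene CHST9 (-0.94), LFNG, which modifies NOTCH receptors (-0.93), the retinoic acid carrier gene CRABP2 (-0.90) and the receptor gene KIT (-0.86). In limma's test 35 genes changed, 27 up and 8 down, of which 21 rose and 4 fell at least 2-fold, and 945 genes had an unadjusted p under 0.05. The count was 10 without control replicate 1, control replicate 2, NANOG replicate 1 or NANOG replicate 2, 9 without OCT4 replicate 1, 13 without OCT4 replicate 2, 147 without SOX2 replicate 1 (95 up and 52 down) and 145 without SOX2 replicate 2. Of 24 named genes that passed, CNRIP1, EBF3, COL5A2, KCNJ2 and ELMOD1 passed with any 1 array left out. The other 19 were lost without some array (16 without control replicate 1, 17 without control replicate 2, 15 without either NANOG array, 16 without OCT4 replicate 1 and 15 without OCT4 replicate 2, at adjusted p up to 0.354), and all 24 kept their sign. With all arrays kept, 8 of these 19 were also lost under another setting, UCP1, LITAF, CHST9, LFNG, CRABP2 and KIT among them. Of 7 called genes with a further probe, LFNG, KIT, TAC1 and CD36 had none that passed.

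Hypoxia and glycolysis genes had a lower median in cells labelled OCT4, with no single member past the threshold. Relative to the control mean, the list median was -0.34 on both OCT4 arrays. It was 0.16 on control replicate 1 and -0.16 on control replicate 2, so the controls lay apart on this list too. Of 28 measured, 22 lay below control, 0 rose and 0 fell, and 3 fell adjusted over the list alone (median log2 change -0.36, camera adjusted p = 1.73e-06; adjusted p = 0.560 with an estimated correlation). Of 28 pluripotency genes 22 lay below control and none passed, with 1 fall adjusted over the list alone (median -0.27, camera adjusted p = 0.00153; adjusted p = 0.375 with an estimated correlation). All 9 measured genes on the metallothionein list lay below control and none passed, with 0 adjusted over the list alone (median -0.34, camera adjusted p = 0.00189, and adjusted p = 0.403 with an estimated correlation). Of 11 germ cell genes KIT fell, also adjusted over the list alone, and 9 lay below control (camera adjusted p = 0.0187; adjusted p = 0.560 with an estimated correlation). Immediate early genes were higher (median 0.18, 10 of 13 above control, 0 past the threshold and 0 adjusted over the list alone, camera adjusted p = 0.0298; adjusted p = 0.672 with an estimated correlation). Outside the called lists, the ERK phosphatase gene DUSP6 (log2 1.27, SE 0.16) and the mesenchymal transcription factor gene TWIST1 (1.22, SE 0.14) rose. The immediate early call ended without control replicate 1, with the direction turned (adjusted p = 0.870), without OCT4 replicate 2 (0.0732) and with only the 2 groups in the fit (0.0501; range 8.58e-06 to 0.870). The germ cell call ended without OCT4 replicate 2 (0.437) and with only the 2 groups in the fit (0.0501; range 0.000136 to 0.437). The number of lists called was 9 without control replicate 1, 10 without control replicate 2 and 9 without OCT4 replicate 1. Calls of KIT, DUSP6 and TWIST1 were lost without some array, at adjusted p up to 0.332. The other 27 lists had adjusted p from 0.0622 to 0.973, and fry called 0 lists.

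In cells labelled SOX2, CH25H and TRIB3 had the largest rises in measured log2 change among the genes that passed, and LDB2 had the largest fall. The rises of WNK4 and CD1C, given below only as bounds, cannot be ranked against these. CH25H, which makes 25-hydroxycholesterol, rose 9.09-fold (log2 3.18, SE 0.28, n = 2 against 2, adjusted p = 0.000726), from 142 and 237 to 1282 and 1339. TRIB3, a pseudokinase induced by amino acid and endoplasmic reticulum stress, rose 8.73-fold (log2 3.13, SE 0.22, adjusted p = 0.000267). SOX21, which fell in cells labelled NANOG, rose 5.82-fold (log2 2.54, SE 0.26, adjusted p = 0.00139). The fibrillin gene FBN2 (log2 2.86), the connexin gene GJA4 (2.73), TAGLN3 (2.69), the noncoding RNA gene MIR503HG (2.59) and the tachykinin gene TAC1 (2.54) also rose, as did the kinase gene WNK4 (at least 4.73-fold) and CD1C, a lipid antigen presenter (at least 5.13-fold). LDB2, a LIM domain binding protein, fell by 3.21 on the log2 scale (SE 0.24, adjusted p = 0.000342), from 1657 and 943 to 180 and 166, and the telomere protein gene TERF1 fell by 2.51 (by 0.53 on a further probe). GDF3 fell by 2.29 on arrays labelled SOX2, where it had risen on those labelled NANOG. The calcium-binding gene S100A4 (-2.26), MT1X (-2.18), MT1G (-2.14), KCNK12 (-2.13), MT1H (-2.10), the adaptor gene AP1S1 (-1.97) and IFITM1 (-1.89) also fell. In limma's test 1382 genes changed, 759 up and 623 down, of which 214 rose and 105 fell at least 2-fold, and 3314 genes had an unadjusted p under 0.05. With only the 2 groups in the fit 204 genes changed, 138 up and 66 down, and with array weights 582, 374 up and 208 down. On SOX2 replicate 2 the probe for 28S ribosomal RNA read 142, against 2770 to 3595 on the other 7 arrays, and that for 18S ribosomal RNA read 750, against 9408 to 12133. The count of genes changed was 1547 without SOX2 replicate 2, 1077 of them among the 1382, and moved further without SOX2 replicate 1 (3517), control replicate 1 (335), control replicate 2 (816), NANOG replicate 1 (607) or NANOG replicate 2 (606). Of 93 named genes that passed, 52 passed with any 1 array left out, and all 93 kept their sign. The other 41, with GDF3, AP1S1 and IFITM1 among them, were lost without some array (38 without control replicate 1, 23 without control replicate 2, 25 without either NANOG array, 11 without SOX2 replicate 2 and 12 without either OCT4 array, at adjusted p up to 0.770). With only the 2 groups in the fit 45 of the 93 were lost, and with array weights 25. With any 1 array left out and under each other setting that gave them a value, 46 passed. Of 33 called genes with a further probe, 16 had none that passed.

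**Figure D3:**
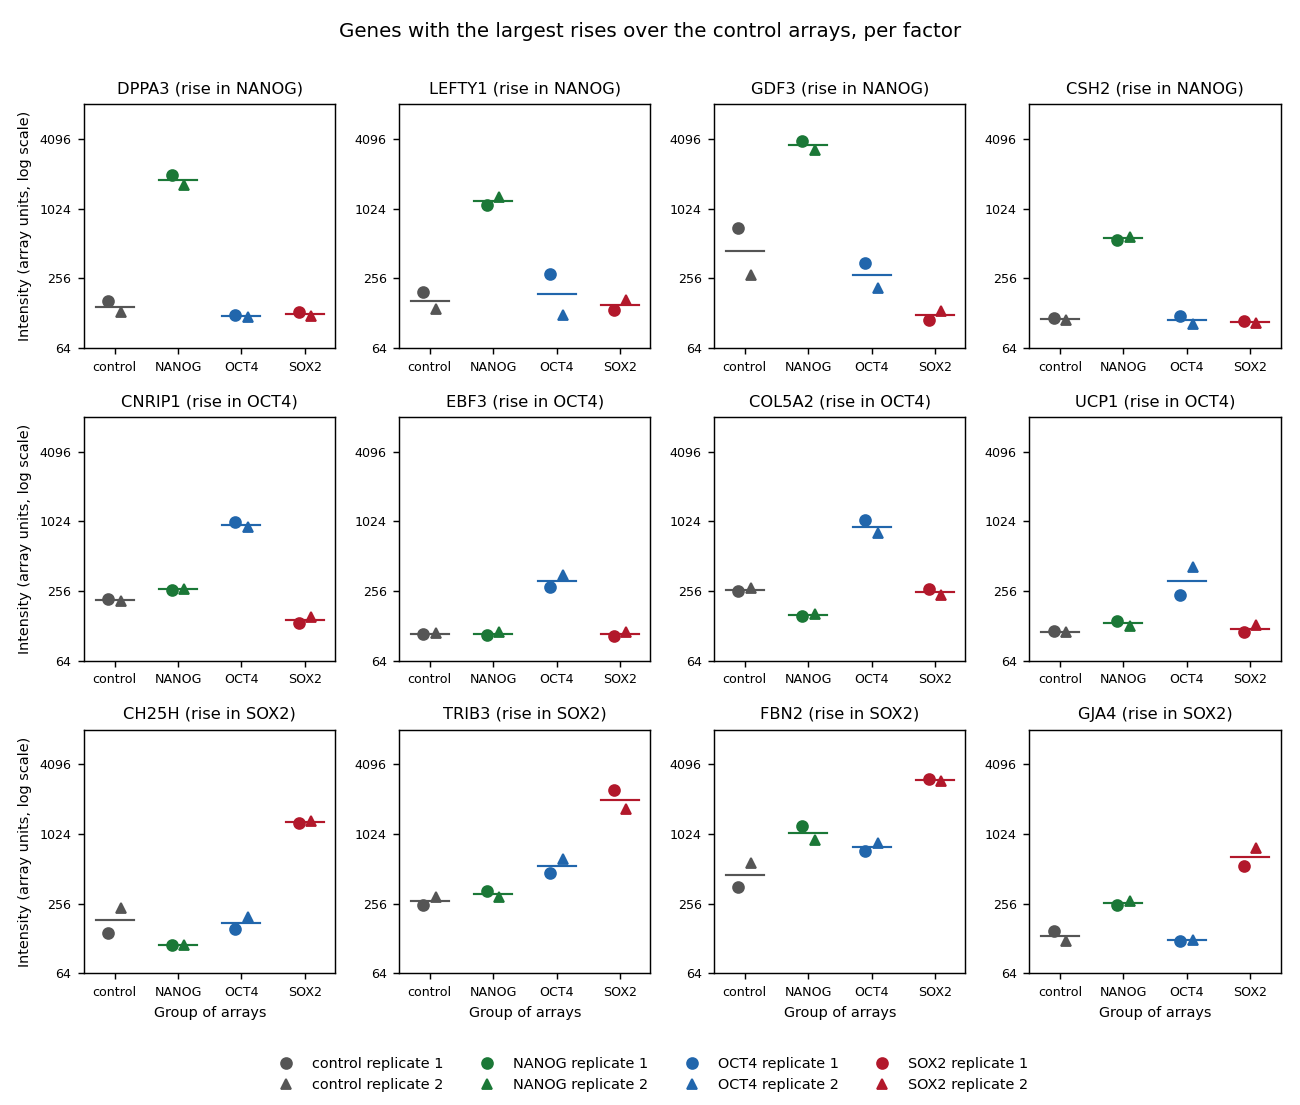
Intensity (linear units on a log axis) on each of the 8 arrays of the 4 genes with the largest rise for each factor against control, by group, with circles for replicate 1, triangles for replicate 2 and a bar at the geometric mean of the 2 arrays. DPPA3 reads 2018 and 1642 on arrays labelled NANOG against 163 and 130 in control, CNRIP1 1008 and 911 against 219 and 212 on arrays labelled OCT4, and CH25H 1282 and 1339 against 142 and 237 on arrays labelled SOX2.

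Of the lists that camera called higher in cells labelled SOX2, none held with an estimated correlation. In the unfolded protein and amino acid stress list, 21 members were measured, of which 10 rose and 1 fell, with 15 and 2 adjusted over the list alone (median log2 change 0.65, camera adjusted p = 9.27e-07; adjusted p = 0.134 with an estimated correlation). Beside TRIB3, the stress transcription factor genes DDIT3 (log2 2.32, SE 0.14), CEBPB (1.60, SE 0.14) and ATF5 (1.38, SE 0.24) rose, and VLDLR, a lipoprotein receptor gene, fell. Of 9 mesenchymal genes 6 rose and 0 fell, also 6 adjusted over the list alone, CDH2 (log2 1.5, SE 0.25), VIM (1.36, SE 0.18), TGFB1I1 (1.36, with a further probe at 0.34) and TGFBI (1.14) among them (median 1.03, camera adjusted p = 0.000152; adjusted p = 0.364 with an estimated correlation). Of 24 interferon response genes 8 rose and 2 fell, with 12 and 2 adjusted over the list alone (camera adjusted p = 0.000198; adjusted p = 0.134 with an estimated correlation). MX1 (log2 1.40, SE 0.13) and HLA-B (1.34, SE 0.13) rose, and BST2 (-1.53, SE 0.19) and IFITM1 fell. Of 25 neuroectoderm genes 7 rose and 0 fell, with 8 adjusted over the list alone (camera adjusted p = 0.0108; adjusted p = 0.637 with an estimated correlation). They included SOX21, the eye and forebrain gene SIX6 (log2 2.20, SE 0.16), the radial glia gene FABP7 (1.64, SE 0.13) and CDH2, the neural cadherin gene, which is on the mesenchymal list as well. Of 13 immediate early genes 3 rose, ATF3 (log2 1.87, SE 0.21), KLF6 (0.97) and FOSL1 (0.73), with 5 adjusted over the list alone (camera adjusted p = 0.00876; adjusted p = 0.631 with an estimated correlation). SOX2 replicate 2, with its 28S probe at 142 against 3129 on replicate 1, gave list medians close to those of replicate 1 for the stress list (0.71 and 0.72). For the mesenchymal (1.2 and 0.85) and neuroectoderm (0.37 and 0.06) lists it was higher than replicate 1. The neuroectoderm call was lost without SOX2 replicate 2 (adjusted p = 0.0631) or control replicate 1 (0.135; range 0.000710 to 0.135). The immediate early call was lost without control replicate 1 (0.164; range 5.46e-05 to 0.164). Among members named here, TRIB3, DDIT3, CEBPB, VIM, TGFB1I1, TGFBI, MX1, HLA-B, BST2, SOX21, SIX6, FABP7, ATF3 and KLF6 passed with any 1 array left out, but VIM was lost with only the 2 groups in the fit. ATF5, CDH2, IFITM1 and FOSL1 did not (adjusted p up to 0.201).

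The lists that camera called lower in cells labelled SOX2 did not hold with an estimated correlation either. Of 28 pluripotency genes 8 fell and 1 rose, with 11 and 2 adjusted over the list alone (camera adjusted p = 0.000152; adjusted p = 0.134 with an estimated correlation). Beside TERF1 and GDF3, DPPA2 (log2 -1.49, SE 0.37) and the DNA methyltransferase gene DNMT3B (-1.33, SE 0.25) fell, and POLR3G rose. Of 9 measured genes on the metallothionein list 6 fell and 0 rose, with 7 falls adjusted over the list alone (median -0.98, camera adjusted p = 0.000152, and adjusted p = 0.134 with an estimated correlation). MT1X fell from 10576 and 6094 to 1467 and 2236. Of 31 cell cycle genes 9 fell and 0 rose, with 12 adjusted over the list alone (camera adjusted p = 3.30e-05; adjusted p = 0.364 with an estimated correlation), CCND1 (log2 -1.42, SE 0.14), the mitotic kinesin gene KIF20A (-1.22), the replication gene MCM4 (-0.94) and CDK1 (-0.77) among them. Of 21 cholesterol synthesis genes 6 fell and 0 rose, with 7 adjusted over the list alone (camera adjusted p = 0.00876; adjusted p = 0.595 with an estimated correlation). They included INSIG1 (log2 -1.01), HMGCS1 (-0.91), MSMO1 (-0.86, with a further probe at 0.09) and SQLE (-0.83). Of 28 hypoxia and glycolysis genes 4 fell, BNIP3 (log2 -1.0), ALDOC (-0.76) and LDHA (-0.74) among them, and the vasoactive peptide gene ADM rose (1.67), with 9 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0148; adjusted p = 0.673 with an estimated correlation). Of 30 oxidative phosphorylation genes 0 passed, also 0 adjusted over the list alone, and 26 lay below control (median -0.16, camera adjusted p = 0.00876; adjusted p = 0.673 with an estimated correlation). The 28S ribosomal RNA probe at 142 on SOX2 replicate 2 stands beside all of these groups. The cholesterol call was lost without control replicate 2 (adjusted p = 0.147) or SOX2 replicate 1 (0.149; range 0.000272 to 0.149). The hypoxia call was lost without control replicate 1 (0.385) or SOX2 replicate 1 (0.143; range 0.000174 to 0.385), and that for oxidative phosphorylation without control replicate 1 (0.164) or SOX2 replicate 1 (0.550; range 0.000104 to 0.550). The number of lists called was 7 without control replicate 1. Calls of TERF1, MT1X, CCND1, KIF20A, MSMO1 and SQLE held with any 1 array left out, but those of MSMO1 and SQLE were lost with only the 2 groups in the fit. Those of GDF3, DPPA2, DNMT3B, MCM4, CDK1, INSIG1, HMGCS1, BNIP3, ALDOC, LDHA and ADM did not (adjusted p up to 0.194). The other 21 lists had adjusted p from 0.0709 to 0.872, and fry called 12 lists, 7 of them called by camera.

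Cells labelled NANOG were compared with cells labelled SOX2 next. GDF3 was 44.8-fold higher with NANOG than with SOX2 (log2 5.49, SE 0.45, adjusted p = 0.000183), ABHD12B 25.9-fold, DPPA3 21.0-fold, EDNRB, the endothelin B receptor gene, at least 14.5-fold and CA4, a carbonic anhydrase gene, 13.7-fold. SOX21 was lower with NANOG by 4.73 log2 units (log2 difference -4.73, SE 0.26, adjusted p = 4.02e-05), CH25H at least 15.6-fold, ADM (log2 -3.27), IGFBP5 (-3.21) and CD44 (-3.01). Metallothionein genes (adjusted p = 3.88e-06), naive pluripotency genes (4.68e-06), pluripotency genes (0.00614), germ cell, nodal, and hypoxia and glycolysis genes (0.00852 each) and oxidative phosphorylation genes (0.0126) were higher with NANOG by camera. Unfolded protein and amino acid stress (3.88e-06), neuroectoderm and mesenchymal (0.000545 each), immediate early (0.0406) and interferon response genes (0.0447) were lower. All 12 calls had an adjusted p of 0.230 or more with an estimated correlation, and the uncalled lists had camera values from 0.0668 to 0.975. In limma's test 2205 genes differed, 1095 higher and 1110 lower with NANOG. The count was 1406 with only the 2 groups in the fit, 601 without NANOG replicate 1, 666 without NANOG replicate 2 and 4005 without SOX2 replicate 1. Of its 2 further probes 1 put ABHD12B higher by 5.53 log2 (adjusted p = 0.00696) and 1 did not pass (0.21). ABHD12B and EDNRB each differed more than 4-fold between the control replicates (4.84-fold and 5.71-fold). The control arrays enter this comparison only through the shared estimate of the spread. EDNRB read 118 and 113 on the SOX2 arrays, under the filter intensity, so only a bound is given for it. ABHD12B and EDNRB were the named genes lost with an array left out: 2 without NANOG replicate 1 and 1 without NANOG replicate 2.

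Between cells labelled NANOG and OCT4, DPPA3 was at least 21.8-fold and GDF3 15.8-fold (log2 3.98, SE 0.45, adjusted p = 0.00181) higher with NANOG, followed by ABHD12B (log2 3.37), EDNRB (3.28) and CA4 (3.25). MEGF10 (log2 -2.99, SE 0.24, adjusted p = 0.000365), COL5A2 (-2.91), SFRP1 (-2.45), ALCAM (-2.23) and the adaptor gene SORBS2 (-2.17) were lower. The OCT4 replicates lay apart for ABHD12B (473 and 140), EDNRB (228 and 122) and SFRP1 (548 and 984), so the sizes of these differences are uncertain. Naive pluripotency and metallothionein genes (camera adjusted p = 5.41e-07 each), germ cell (3.74e-06), hypoxia and glycolysis (0.000116), nodal (0.00140), primitive streak (0.0112) and trophectoderm genes (0.0254) were higher with NANOG. Cell cycle (0.00168) and unfolded protein and amino acid stress genes (0.0296) were lower. All 9 calls had an adjusted p of 0.218 or more with an estimated correlation, and the uncalled lists had camera values from 0.0842 to 0.981. In limma's test 890 genes differed, 537 higher and 353 lower with NANOG. With only the 2 groups in the fit 1243 were higher and 1276 lower, and with array weights 1231 were higher and 1267 lower. The count was 129 without NANOG replicate 1, 187 without NANOG replicate 2, 465 without OCT4 replicate 1, 248 without OCT4 replicate 2 and 1889 without SOX2 replicate 1 or SOX2 replicate 2. ABHD12B, EDNRB and SFRP1 were lost with an array left out (all 3 without NANOG replicate 1, NANOG replicate 2 or OCT4 replicate 2 and 1 without OCT4 replicate 1, at adjusted p up to 0.253), and the other 7 named genes were not. ABHD12B was also lost with the offset of 16 and with no filter, and neither of its further probes passed.

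Between cells labelled OCT4 and SOX2, LDB2 was 9.27-fold (log2 3.21, SE 0.24, adjusted p = 0.000345) and CNRIP1 8.99-fold higher with OCT4, followed by the neuronal RNA-binding gene ELAVL2 (log2 2.49), the protocadherin gene PCDH18 (2.23) and LRRC3B (2.18). CH25H (log2 -3.27, SE 0.28, adjusted p = 0.000610), TAGLN3 (-3.13), GJA4 (-2.91), SOX21 (-2.88) and IGFBP5 (-2.74) were lower, and all 10 calls held with any 1 array left out. Cell cycle (camera adjusted p = 3.90e-05) and metallothionein genes (0.00509) were higher with OCT4. Unfolded protein and amino acid stress (2.33e-06), interferon response (3.90e-05), neuroectoderm (0.00196) and mesenchymal genes (0.00432) were lower. All 6 calls had an adjusted p of 0.212 or more with an estimated correlation, and the uncalled lists had camera values from 0.0558 to 0.874. In limma's test 858 genes differed, 372 higher and 486 lower with OCT4. With only the 2 groups in the fit 54 were higher and 131 lower, and with array weights 158 were higher and 288 lower. The count was 377 without NANOG replicate 1, 374 without NANOG replicate 2, 3274 without SOX2 replicate 1, 237 without OCT4 replicate 1 and 277 without OCT4 replicate 2.

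Changes against control were then compared between factors. All 3 groups had higher CD36, a fatty acid transporter gene (log2 1.21, 1.13 and 0.83 for NANOG, OCT4 and SOX2), and higher GLTP, a glycolipid transfer protein gene (0.54, 1.33 and 0.79), and all 3 had lower LFNG by 1 of its 2 probes (-0.88, -0.93 and -0.87). The other LFNG probe did not pass for any factor (-0.11, -0.09 and -0.03), and a further CD36 probe passed for NANOG (1.27) but not for OCT4 (0.91) or SOX2 (0.50). The LFNG call for OCT4 was also lost under 5 of 10 alternatives with all arrays kept, and the SOX2 calls of LFNG, CD36 and GLTP were lost with only the 2 groups in the fit. That setting also ended the OCT4 call of CD36, and 4 other settings ended the NANOG call of GLTP. The LFNG and CD36 calls were lost for each factor without at least 1 array, and those of GLTP for NANOG and OCT4, at adjusted p up to 0.329. NANOG and SOX2 moved 84 genes in the same direction, 50 up, with SPOCK2, IGFBP3, FBN2, GJA4 and UPP1 the largest by mean change, and 34 down. The further UPP1 probe passed for neither factor (log2 0.04 and 0.47), and the SPOCK2 call for SOX2 was lost with array weights. Independent lists of these sizes would share 20.8 up and 5.51 down. A further 53 moved in opposite directions, 44 of them up with NANOG and down with SOX2 (17.1 for independent lists) and 9 the reverse (6.71). OCT4 and SOX2 shared 10 rises, with TAC1, DUSP6 and KCNJ2 among them, and 5 falls, CHST9, HESX1, KCNK12, KIT and LFNG (1.65 and 0.401 for independent lists). For OCT4 the further probes of TAC1 (log2 0.43 and 1.02) and KIT (-0.54) did not pass, and the SOX2 call of KCNJ2 was lost with only the 2 groups in the fit. CNRIP1 (log2 -0.76 with SOX2) and the kinase gene FER (1.18 with OCT4 and -0.73 with SOX2), named after their values were seen, rose with OCT4 and fell with SOX2, where independent lists would give 1.35 such genes. NANOG and OCT4 shared 4 rises (CD36, GLTP, KCNE5 and NSG1) and 3 falls (LFNG, RPRML and CRABP2) (0.740 and 0.0708 for independent lists). Opposite changes, named after their values were seen, were in CHST9, HESX1 and KCNK12 (log2 0.87, 0.66 and 0.97 with NANOG), which fell with OCT4, and in COL5A2 (-0.92 with NANOG), which rose with it (0.219 and 0.239 for independent lists). Unchanged groups simulated against shared controls gave a mean of 0 (NANOG and OCT4), 0.02 (NANOG and SOX2) and 0.05 (OCT4 and SOX2) genes in the same direction. No gene was changed in that simulation and its noise was independent between genes, so almost no calls could arise. These counts therefore cannot size the effect of the shared controls. The 2 control arrays could not be split into sets of 2, so part of the excess may come from the shared controls. Across genes, which are not independent replicates, fold changes correlated at 0.04, 0.06 and 0.38 for these pairs, against 0.50 in simulation. Their covariances were 0.00281, 0.00848 and 0.0327 against simulated values of 0.0138, 0.0137 and 0.0138, which leaves differences of -0.0110, -0.00526 and 0.0189. The 0.50 follows from shared controls when no gene changes, and changes in 1 group alone lower it, so it is no baseline. The simulated covariances rest on a spread pooled over all groups, with the wide SOX2 spread in it, and not on the controls' own. Neither the correlations nor the covariance differences can therefore separate shared responses from shared controls. In order of control replicates 1 and 2, NANOG 1 and 2, OCT4 1 and 2, and SOX2 1 and 2 left out, the genes in the same direction for NANOG and OCT4 numbered 0, 0, 0, 0, 0, 1, 27 and 26, and for OCT4 and SOX2 2, 4, 2, 2, 2, 5, 65 and 64. For NANOG and SOX2 they numbered 42 without control replicate 1, 14 without control replicate 2, 3 without NANOG replicate 1, 8 without NANOG replicate 2, 271 without SOX2 replicate 1 and 179 without SOX2 replicate 2.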

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

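The tests of probes that name no gene were chosen only after the main results had been seen. Of 21828 probes past the filter, 5364 carried no gene name and entered none of the gene comparisons. In a fit over all probes, 36 of them were higher on the arrays labelled NANOG than in control, 3 on those labelled OCT4 and 108 on those labelled SOX2, and 15, 0 and 106 were lower. The share of unnamed probes that changed was 0.951% with NANOG, 0.0559% with OCT4 and 3.99% with SOX2, against 2.76%, 0.213% and 9.32% of named probes. What these probes measure was not analysed here, and no explanation was tested.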

How the results depend on the processing

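An offset of 16, a filter on all 8 arrays and the omission of SOX2 replicate 2 were chosen after seeing the data, and all other alternatives were planned. Scaling to a percentile, filters on detection p-values and slide as a block were not run, because the values were already quantile normalized, detection p-values could not be assigned to samples and slides are not given in the sources used here. Over all alternatives, counts of genes and lists stayed within 1.5 times 129 times and moved further 84 times. Calls of single lists against control kept their direction and side of the threshold 373 times, lost significance 47 times and reversed 1 time, and named genes did so 3325, 641 and 1 times, with 5 gains. Lists measured in fewer than 5 genes after the filter on all 8 arrays gave no value.

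With the filter on all 8 arrays, genes changed numbered 238 (NANOG), 16 (OCT4) and 590 (NANOG against OCT4), shared changes 4 (NANOG and OCT4) and 7 (OCT4 and SOX2), and NANOG lists 5; fewer genes were tested there. With only the 2 groups compared, counts were 1221 (NANOG), 204 (SOX2), 2519 (NANOG against OCT4), 1406 (NANOG against SOX2) and 185 (OCT4 against SOX2), shared changes 47 (NANOG and SOX2) and 5 (OCT4 and SOX2), OCT4 lists 3, and SOX2 probe ILMN_2177156 was at -1.15 with adjusted p = 0.0911 (0.00840 with all groups); comparisons without the SOX2 arrays then leave out that group's wide spread, and those with them rest on it. Array weights gave 1272 (NANOG), 99 (OCT4), 582 (SOX2), 2498 (NANOG against OCT4) and 446 (OCT4 against SOX2), shared changes 17 (NANOG and OCT4) and 32 (OCT4 and SOX2), and POU5F1 probe ILMN_1705546 passed at -0.95 (adjusted p = 0.0156); the cause was not tested. The offset of 16 gave 4 shared changes for NANOG and OCT4, and no background correction gave 9 for OCT4 and SOX2; the cause was not tested. The share of rises among OCT4 calls was 77.1%, but 87.5% with no background correction, 65.7% with array weights (65 up and 34 down) and 64.6% without SOX2 replicate 1. For NANOG it was 75.6%, but 59.8% with only the 2 groups compared and 58.4% with array weights, and for SOX2 54.9%, 67.6% and 64.3%. The share higher with the first factor was 60.3%, 49.3% and 49.3% for NANOG against OCT4 and 43.4%, 29.2% and 35.4% for OCT4 against SOX2 in the same order. With an estimated correlation, 0 lists were called for any factor.

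With 1 array left out, the lone array of its group is assumed to vary like the others. Counts then ranged from 49 to 1094 (NANOG), 9 to 147 (OCT4), 335 to 3517 (SOX2), 129 to 1889 (NANOG against OCT4), 601 to 4005 (NANOG against SOX2) and 237 to 3274 (OCT4 against SOX2). Shared changes ranged from 0 to 27 (NANOG and OCT4), 3 to 271 (NANOG and SOX2) and 2 to 65 (OCT4 and SOX2), and lists from 8 to 9, 5 to 10 and 7 to 12 for NANOG, OCT4 and SOX2. Leaving out a SOX2 array removes that group's wide spread from the pooled estimate. Of the factor probes given next, POU5F1 probe ILMN_1665632 lay close to the filter intensity, so its sign cannot show whether POU5F1 changed. Probe changes on a factor's own arrays ranged from -0.47 to 0.04 (ILMN_1659013) and -0.42 to -0.16 (ILMN_3307710) for NANOG, -0.22 to 0.19 (ILMN_1665632) and -1.09 to -0.80 (ILMN_1705546) for POU5F1, and -1.12 to -0.42 (ILMN_1770635) and -1.40 to -0.90 (ILMN_2177156) for SOX2. Signs turned for ILMN_1659013 without control replicate 1 (0.04), for ILMN_1665632 without control replicate 2 (0.03) or OCT4 replicate 2 (0.19), and for the OCT4 immediate early list without control replicate 1 (adjusted p = 0.87, over a range from 8.58e-06 with arrays left out); the cause was not tested.

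No label says that replicate numbers pair the samples. Deviations of same-numbered arrays correlated across genes from -0.19 (control and SOX2) to 0.38 (control and OCT4). With the replicate block, counts were 394 (NANOG), 32 (OCT4), 1197 (SOX2), 783, 2125 and 760 (NANOG against OCT4, NANOG against SOX2, OCT4 against SOX2), shared changes 6, 68 and 11, and lists 9, 5 and 11, and SOX2 probe ILMN_1770635 passed at -0.77 (adjusted p = 0.0353). The number of arrays and the signal over background limit what could be seen: an intensity of 123.7 lies close to the smallest of 86.3.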

Other observations

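All tests of explanations in this part were chosen only after the results had been seen. The gene lists described first were fixed before the data were examined.

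Several developmental genes changed outside the lists that camera called. In cells labelled SOX2, the endoderm list had 3 rises among 12 genes (5 rises and 1 fall adjusted over the list alone): the transcriptional repressor gene PRDM1 (at least 3.30-fold), TM4SF1 (log2 1.80, SE 0.23) and the chemokine receptor gene CXCR4 (1.06, SE 0.15). Camera gave an adjusted p of 0.0709 (adjusted p = 0.364 with an estimated correlation), and fry 0.00911. On the HOX list, which also holds MEIS1 and MEIS2, HOXD1 was the 1 measured gene of 5 to rise past the threshold. It rose at least 1.93-fold, and all 5 lay above control. For the HOX list camera gave an adjusted p of 0.0744 (adjusted p = 0.366 with an estimated correlation), and fry 0.00195. BMP signalling targets moved both ways (camera adjusted p = 0.785): ID1 (log2 -1.26, SE 0.15, with a further probe at -0.23), ID3 (-1.0) and SMAD6 (at least 1.68-fold lower) fell and DLX5 rose (1.10). Heat shock genes did so as well (adjusted p = 0.554), with HSPA1A up (log2 1.34, SE 0.13) and HSPA4 (-1.04), HSPE1 (-0.49) and HSPA8 (-0.47) down. Of 20 p53 targets 4 rose and 2 fell, also 4 and 2 adjusted over the list alone: GADD45A (1.01) and SESN2 (1.04) were among the rises, and RRM2B (-1.49) and BAX (-0.82, with a further probe at 0.24) fell (adjusted p = 0.785). Markers of other cell types gave no list call: among fibroblast genes ACTA2 rose (0.55) and S100A4 (-2.26) and COL1A2 (-0.84) fell (adjusted p = 0.785), and among blood and endothelial genes CD74 rose (0.88; adjusted p = 0.554). On SOX2 replicate 2 the 28S probe read 142. Without some array, SMAD6, HSPA4, HSPE1, HSPA8, GADD45A, SESN2, RRM2B, BAX, ACTA2, COL1A2 and CD74 were lost (adjusted p up to 0.770), and the other genes named here were not. Further probes of COL1A2, CD74, HSPE1 and HSPA8 did not pass.

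In cells labelled NANOG, BMP targets ID2 (log2 -1.26, SE 0.27), ID3 (-0.97, SE 0.12) and DLX5 (-0.65) fell and none of the 9 rose past the threshold (camera adjusted p = 0.279, adjusted p = 0.522 with an estimated correlation, fry 0.0367). Adjusted over the list alone, 3 fell and 1 rose. Of the endoderm genes, APOB rose at least 1.82-fold and CXCR4 rose (log2 0.88) (adjusted p = 0.411). Of 24 interferon response genes, HLA-B (0.85) and IFIT3 (at least 1.49-fold) rose, and BST2 (-0.86) and IFIT1 (-0.52) fell (camera adjusted p = 0.123, adjusted p = 0.340 with an estimated correlation, fry 0.0338). Of these genes APOB passed with any 1 array left out, and the others were lost without some array (adjusted p up to 0.397). Other settings with all arrays kept also ended calls of ID2, DLX5, BST2 and IFIT1, and a further IFIT3 probe did not pass (0.25). The ribosomal protein, chromatin regulator, imprinted gene, mesoderm, neural crest, epithelial, WNT and NOTCH lists were also uncalled by camera in each comparison with control. Their camera adjusted p ran from 0.164 upwards. With SOX2, however, fry called the WNT and imprinted gene lists higher (adjusted p = 0.0322 each). It also called the trophectoderm and amnion list higher there (fry adjusted p = 0.0220, camera adjusted p = 0.349). Against control, median, mean and test differed in sign for some uncalled lists. With NANOG these were pluripotency (median -0.13, mean 0.12, test down), neural crest (-0.07, 0.21, down), immediate early (-0.01, -0.09, up), blood and endothelium (0.05, -0.09, up), epithelial (0.04, -0.02, down), WNT (0.02, -0.01, down) and mesoderm. With OCT4 they were imprinted genes (0.01, -0.03, up), mesoderm (0.03, 0.04, down) and neural crest (-0.02, 0.08, up), and with SOX2 imprinted genes (-0.06, 0.05, up), p53 targets (-0.01, 0.00, up) and germ cell genes (0.04, 0.04, down).

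Replicates 1 and 2 differed in the same genes in the control and OCT4 groups: for example, replicate 1 over replicate 2 was 2.52-fold and 4.72-fold for NODAL, 4.84-fold and 4.41-fold for ABHD12B, and 0.324-fold and 0.304-fold for EGR1, genes named after their values were seen. A batch that follows the replicate number in all 4 groups would make same-numbered arrays deviate alike in every pair of groups. Deviations correlated across genes at -0.19 (control), -0.11 (OCT4) and 0.14 (NANOG) with those of SOX2. SOX2 replicate 2 differed widely from replicate 1, so these values cannot decide. Between control and NANOG the correlation was -0.01, and between NANOG and OCT4 0.02, which shows no such shared deviation in the NANOG group. The loss of ribosomal RNA signal seen on SOX2 replicate 2 is argued against. In the authors' intensities the 28S probe differed by at most 1.18-fold between the replicates of the control and OCT4 groups. As a hypothesis, the cultures may have lain at different points of the axis along which the arrays labelled NANOG moved: across genes, OCT4 replicate 1 minus replicate 2 correlated at 0.35 with NANOG minus control. For control replicate 1 minus replicate 2 the value was 0.39, though both sides of it use the control arrays. Whether part of the nodal change on the arrays labelled NANOG reflects such a difference between cultures was not tested. A batch shared by the control and OCT4 groups alone was not tested and stays open.

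No probe of a transduced factor rose on its own arrays. An exchange of labels between groups cannot be excluded, as the largest log2 rise of any of the 6 probes in any group was 0.31. Probes that lie outside the transduced sequence could also account for the lack of a rise. Log2 changes of the 6 probes on their own arrays ran from -1.15 (SOX2 probe ILMN_2177156) to -0.014 (the dim POU5F1 probe ILMN_1665632). As ILMN_1665632 lay close to the filter intensity, its value cannot bear on either explanation. Without it, the highest value was -0.22 (NANOG probe ILMN_1659013). Both explanations stay open because the probe positions are not given in the sources used here. Lower expression of the cells' own copy of the gene in response to the vector was not tested and stays open as well.

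The arrays labelled SOX2 differed from control and from each other. Whether the changes come mainly from replicate 2 cannot be decided from counts of genes. Without replicate 2, 1547 genes changed, but that fit rests on 1 SOX2 array and leaves out the group's wide spread. The count was higher still without replicate 1. The 1382 genes found with both arrays were selected with replicate 1 included, so their overlap with the 1547 is no separate evidence. In the authors' intensities, without background correction, the 28S probe was 22.1-fold and the 18S probe 12.5-fold lower on replicate 2 than on replicate 1. Lower RNA quality on replicate 2 may set the difference between these 2 arrays. No measure of RNA quality is given in the sources used here, and these probes alone do not show it. With 1 array of each kind this cannot be told apart from a difference between the cultures.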
